A study of Arabidopsis thaliana with 5 samples.

How the data were processed

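Root protoplasts of Arabidopsis thaliana seedlings were profiled 5 days after germination by droplet single-cell RNA sequencing in 5 libraries: 3 of wild type (WT, Columbia-0), 1 of rhd6 and 1 of gl2. Groups were taken from the sample labels, which give 1 library per mutant. The authors deposited 1 merged table of raw UMI counts per gene and cell, with 21965 genes and 11030 cells; each cell's name begins with its library, and no column was left without a library. Per the submitters' processing notes, reads were processed with Cell Ranger 2.1.1 against the TAIR10 genome; the annotation, the rule for calling cells and the merging step are not given in the sources used here. The counts are whole numbers that were not normalised. In every library a gene had counts in no cell or in at least 3 cells, so a library's 0 can stand for a few counts that were left out before deposit. Each floor used here is 3 counts and assumes that no more than that was left out. Intervals and floors cover counting error only.

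The libraries held between 43782514 and 156431623 UMIs, with between 8012 and 14596 UMIs in their shallowest cells. No cell was removed for depth. Mitochondrial transcripts made up at most 0.171% of any cell's UMIs, so no cell was removed for them either. Chi-square tests of counts over genes gave between 67.9 and 190.6 per degree of freedom for the 3 pairs of WT libraries, far above sampling noise, so each WT library was counted as its own replicate. The labels do not say whether the WT libraries came from separate plantings, and p-values therefore measure the spread between these libraries, which may be technical.

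Doublets were treated by a second procedure: the caller Scrublet was run first and marked too few cells to count as working. In its place, doublets were simulated by adding pairs of cells within a library, each cell was scored by the share of simulated doublets among its neighbours, and the highest-scoring cells were removed at an assumed 0.8% per 1000 barcodes. This removed 252 cells and kept 10778. The whole-root fit had been looked at once before this change. The removed cells did not hold more UMIs in every library (medians of 23959 among removed and 27440 among kept cells in WT replicate 1, and 35914.5 and 31146 in rhd6), so doublets may remain among kept cells.

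For the whole-root comparisons, raw counts were summed over the kept cells of each library and tested with edgeR 4.0.16 (R 4.3.3): TMM normalisation, filterByExpr, glmQLFit and glmQLFTest, with all 5 libraries in 1 fit and 3 groups. Only the 3 WT libraries give a spread (2 residual degrees of freedom); each mutant library was assumed to vary like them. "edgeR adjusted p" stands for this quasi-likelihood test with Benjamini-Hochberg adjustment, and genes under 0.05 were called. Genotype, library and accession background differ together and cannot be told apart by this design. Levels are CPM, the usual scaled counts, of the summed counts over TMM-scaled library sizes, with SD over the 3 WT libraries. Floors of a level and ratios of few counts use the same sizes; a floor is 3 counts in a mutant library or over the 3 WT libraries together. The same test was run on counts summed per library and cell class where each library had at least 20 cells, and on hair-like against non-hair-like sums of the 3 WT libraries with the library as a block.

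Cells were clustered in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, igraph 0.11.9) on 2000 highly variable genes, 40 principal components, 20 nearest neighbours and the Leiden method at resolution 1. The genes of all lists and the 6162 genes called in a mutant against WT were left out of the features, 6254 in all. This was done to keep cluster sizes from resting on the called genes. Genes that differed without a call, or were called only between the mutants, could still be features, so clusters can still part by library. A cluster took the class whose markers had the highest mean log2 fold over the other cells, computed with 5 CPM added, if that mean was above 1, at least 3 markers were detected, and no other class had more markers among its top 10 genes; otherwise it stayed unnamed. This rule and the clustering settings were set after the table was read and before any cluster was seen, and were not changed afterwards. There were 28 clusters, of which 12 were named, in 7 classes. The markers of dividing cells took no part in this rule, so no cluster could be named for them. No cluster took the stele class. Shares of cells with hair marker transcripts were taken after each cell was thinned to 2000 UMIs, which left no cell out, and phloem-like cells stand in the place of the planned stele-like cells as background.

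Gene lists, cell type markers, designs, alternatives and the rule for named genes were fixed before the data were examined. The naming lists hold markers of hair, non-hair, cortex, endodermis, root cap, xylem, phloem, stele and dividing cells; the test lists hold root hair growth genes, epidermal patterning regulators, iron uptake, nitrate uptake and assimilation, wounding and defence response, heat shock, suberin synthesis, auxin response, ethylene response, glucosinolate synthesis and DNA replication. The table names genes by symbol or locus. Of its 21965 genes, 18488 were matched to a locus of the TAIR10.1 reference annotation, 13 of them through aliases written after the table's names were seen; matches out of genome order were dropped. List members that the table does not name were not analysed here. The result of 1 stele marker is not reported. For each list, the members past the threshold were counted with adjustment over all genes tested and with adjustment over the list alone, and the median log2 fold change was set among 10000 random lists of the same size matched on expression, as a description.

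Named genes are RHD6 and GL2; the 8 largest rises and falls per mutant against WT among called genes with a symbol, at least 20 CPM in the higher group and a mutant value outside the WT range; up to 4 members of each test list with the smallest adjusted p; the 8 largest rises and falls between hair-like and non-hair-like cells; and the 3 largest rises and falls within each class. Other list members are named where they passed the test, a choice made after their values were seen. Reads of near-identical gene copies can be split or lost in 3' counting, so SUC7, AT1G24880, LSU1, LSU2 and the GSTU genes are reported as uncertain, and the mutants' accessions differ in sequence from the Columbia reference, which can also lower a count.

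The alternatives tried were DESeq2 1.42.0 size factors and Wald test, no filter on low counts, each WT library left out in turn, all deposited cells, libraries thinned to 1 total, the mean over cells of counts per 10000 UMIs with a pseudocount of 0.01 tested with limma 3.58.1, all highly variable genes, resolutions 0.5 and 1.5, centring within libraries, doublet calls kept, no library block, and other settings of the hair marker share. Scripts were tested on simulated data with 200 changed genes each. The whole-root test of rhd6 against WT, on 18868 genes, recovered 32% of changes of 1.5 and 85% of changes of 3 on the log2 scale. It made 18 false calls, a larger share of its calls than the threshold of 0.05 aims at. Whole-root counts may therefore hold more false calls than that threshold implies. The hair against non-hair test, on 13759 genes, recovered 91% and 100% with 10 false calls. Chosen only after values were seen were the comparison of each WT library with the other WT libraries as if it were a mutant, the test of whether a change differed between classes, the 32-fold and 8-fold limits in the tests of explanations, and the tests of gene positions, of cortex-like shares and of fewer endodermis cells.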

Results

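Single-cell transcriptomes were collected from Arabidopsis thaliana roots 5 days after germination, as protoplasts, cells whose walls had been digested. Root epidermal cells of wild type (WT) either grow a hair or stay hairless. The series compared WT with rhd6, a mutant without root hairs, and gl2, a mutant with excess root hairs, to see how the cells of each root differed. RHD6 is a transcription factor that starts hair growth, and GL2 is a homeodomain factor that represses hair fate in non-hair cells. There were 3 WT libraries in the Columbia-0 accession, 1 rhd6 library in a mixed Columbia/Ws background and 1 gl2 library in Landsberg erecta. WT replicates 1, 2 and 3 held 4406, 1473 and 1643 cells and 156431623, 43782514 and 44786899 UMIs (counted transcript molecules). The rhd6 library held 2505 cells and 98462625 UMIs, and the gl2 library 1003 cells and 47811586 UMIs. Median UMIs per cell were 27299.5, 23041 and 21586 in the WT libraries, 31193 in rhd6 and 29514 in gl2. With 1 library per mutant, a difference from WT had no replicate check on the mutant side, and genotype, library and accession background changed together.

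RHD6 (BHLH83, AT1G66470; TAIR10.1 chromosome 1, 24795214 to 24797015, plus strand) stood at 26.0, 8.33 and 8.45 CPM in WT replicates 1 to 3, 1.37 CPM in rhd6 and 30.6 CPM in gl2. It was lower in rhd6 than in WT, with a log2 fold change of -3.38 (SE 0.887, edgeR adjusted p = 0.0489). That call was narrow: the edgeR adjusted p was 0.0589 without WT replicate 2, 0.0549 without WT replicate 3, and the adjusted p ranged from 5.4e-06 (DESeq2) to 0.173 (limma) over all alternatives. RHD6 was not called in gl2 (log2 fold change 1.09, edgeR adjusted p = 0.28), but was called without WT replicate 1 (1.87, edgeR adjusted p = 8.84e-05). GL2 (AT1G79840; TAIR10.1 chromosome 1, 30036956 to 30041440, plus strand) stood at 1.33, 0.785 and 1.19 CPM in WT replicates 1 to 3, 0.378 CPM in rhd6 and 2.5 CPM in gl2. Its transcript was thus not lower in the gl2 library (log2 fold change 1.17, SE 0.423, edgeR adjusted p = 0.107; 0.0434 without WT replicate 1, and from 0.0434 to 0.222 over all alternatives), nor did it pass the test in rhd6 (-1.55, edgeR adjusted p = 0.083). The labels do not give either allele's lesion, and 3' transcript tags need not be lost from a mutated gene, so these levels do not check the labels.

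Genes of hair growth were far lower in the rhd6 library than in WT. Of 23 root hair growth genes measured, 20 fell and none rose (21 fell when adjusted over the list alone); their median log2 fold change was -5.09, below that of all 10000 matched random lists. The cell wall protein gene RHS4 fell from 51.6 ± 15 CPM (SD, n = 3) to 0.0801 CPM, MRH6 from 36.6 ± 13.7 to 0.664 CPM, and GEF4, an activator of ROP GTPases in hair initiation, from 41.0 ± 11.1 to 2.27 CPM. RHS16 fell from 26.0 ± 9.19 to 0.675 CPM. All 6 hair naming markers fell as well, among them EXPA7 (log2 fold change -6.00) and the hair growth regulator RSL4 (-4.43).

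**Figure D1:**
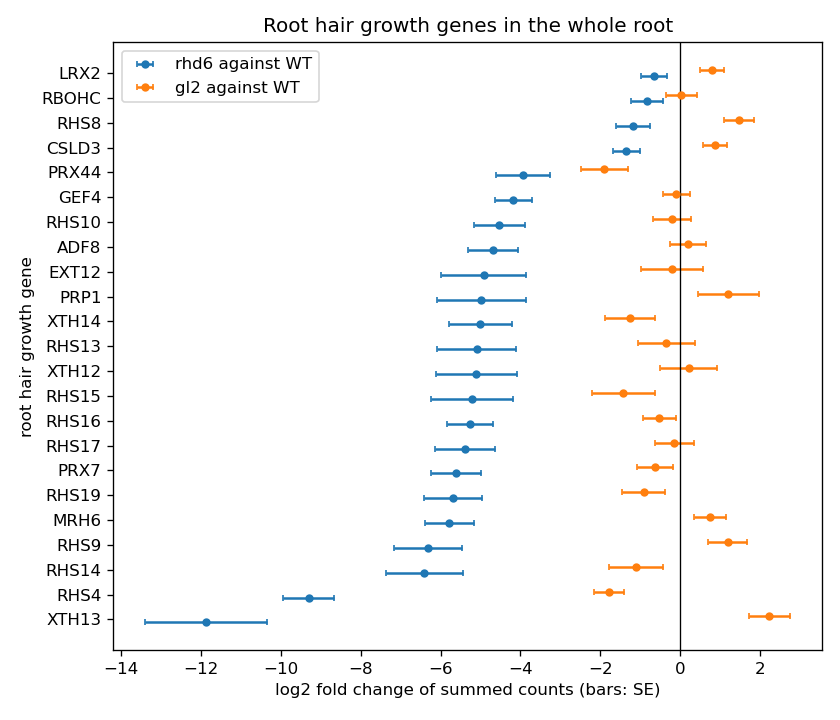
Log2 fold change of summed counts (x axis) for each of the 23 root hair growth genes (y axis), rhd6 against WT in blue and gl2 against WT in orange, with bars of 1 SE. All 23 blue points lie below 0, with a median of -5.09, and the orange points lie on both sides of 0, with a median of -0.15.

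Further groups also moved in rhd6. Of 14 epidermal patterning regulators, 5 fell and none rose, among them RHD6 itself, RSL2 (log2 fold change -5.40, SE 0.561, edgeR adjusted p = 0.00618), LRL3 (-3.77), the non-hair factor gene MYC1 (-4.17) and ETC1 (-1.87); 5 fell when adjusted over the list alone, and the list's median was -1.32. Without WT replicate 3, 3 of the 14 fell. Of 8 ethylene response genes, 5 rose and none fell (7 rose when adjusted over the list alone; median 1.77). These were the F-box genes EBF1 (log2 fold change 2.1) and EBF2 (2.11), which limit ethylene signalling, and the receptor genes ERS1 (1.60), ERS2 (1.94) and ETR2 (2.1). Of 10 iron uptake genes, 5 rose and 2 fell, with the same counts when adjusted over the list alone (median 0.95). The iron deficiency regulators BHLH38, BHLH39 (from 1.40 ± 1.05 to 26.0 CPM) and BHLH101, the scopoletin synthesis gene F6H1 (7.82 ± 3.42 to 59.9 CPM) and the exporter PDR9 rose, while MYB10 and the ferritin gene FER1 (log2 fold change -1.82) fell. BHLH38 was near the floor in WT, with 4 UMIs in all. Without WT replicate 2, 2 iron genes rose and 1 fell; without WT replicate 3, 3 rose and 1 fell. Of 9 nitrate genes, 3 rose (GLN1;2, NRT1.1 and NIA2; log2 fold changes 2.45, 1.44 and 1.47) and none fell; adjusted over the list alone, 4 rose and 1 fell, and the median was 0.76 while the mean was -0.04. Without WT replicate 3, 1 nitrate gene rose.

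Members of further lists also passed the test in rhd6. Of 12 wounding and defence genes, MYB51 rose (log2 fold change 1.07) while WRKY40 (-1.35) and WRKY33 (-1.29) fell, with the same counts over the list alone (median -0.27). Of 4 heat shock genes, DREB2A fell (-1.61), and 2 fell when adjusted over the list alone (median -1.5). Of 11 auxin genes, the auxin transporter gene PIN2 rose (1.01) and IAA19 fell (-1.39), with the same counts over the list alone (median -0.75). Of 8 glucosinolate genes, MAM3 and CYP79F1 had no count in rhd6 and were at least 80.2-fold and 36.3-fold lower; 3 fell when adjusted over the list alone (median -0.76). Of 5 DNA replication genes, CDT1A (-2.02) and MCM5 (-1.55) fell, and 3 fell when adjusted over the list alone (median -1.35). None of 3 suberin genes passed the test, and 2 fell when adjusted over the list alone; their median was -6.37, or -2.01 with the 2 genes without counts at their bound. Without WT replicate 3, MYB51, WRKY33, PIN2, IAA19, NRT1.1, NIA2, CDT1A, MCM5, ETC1 and CYP79F1 missed the threshold, and without WT replicate 2 BHLH39, MYB51, WRKY33, PIN2, CYP79F1 and MCM5 did. Among markers of other cell types, the xylem genes XCP1, XCP2 and CESA4 rose and ACL5 fell (median of 9 markers 1.51). With edgeR, 6 of the 9 rose without WT replicate 1 and 0 without WT replicate 2 or 3. The endodermis marker SCR rose and 8 of 9 endodermis markers did not pass the test (median 0.82). AT1G66800 rose and CPC fell among 6 non-hair markers, and NPF6.4 (cortex), NAC045 (phloem), AHK4 (stele) and CDKB1;1 (dividing) fell (medians -0.26 for non-hair, -0.40 or 0 with genes without counts at their bound for cortex, 0.73 for phloem, -0.14 for stele and -0.63 for dividing markers). None of 5 root cap markers passed the test (median -0.55). All of these were fixed as cell type markers, so they also move with the mix of cells.

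In all, 3893 of 19673 genes tested differed between rhd6 and WT, 2034 higher and 1859 lower. Among the largest rises were PDF2.4, a defensin-like gene (0.113 ± 0.108 to 140 CPM), GASA5 (0.271 ± 0.116 to 28.8 CPM), the methyltransferase gene PXMT1 (2.23 ± 1.09 to 88.8 CPM), the amino acid transporter gene AAP4 (2.77 ± 1.98 to 76.9 CPM) and the expansin gene EXPA17 (24.3 ± 11.0 to 592 CPM). C/VIF1 and GSTU24 rose too (22.6-fold and 19.2-fold), and the sucrose transporter gene SUC7 had 2190 UMIs in rhd6 against 3 in WT, a ratio of 1996 (95% counting interval 682 to 9684). Among the largest falls, GSTU14 and CID5 had no count in rhd6 and were at least 961-fold and 604-fold lower. MRD1 fell from 54.8 ± 5.84 to 0.0687 CPM, NSP3 from 41.9 ± 10.0 to 0.126 CPM, TET12 from 32.6 ± 13.7 to 0.206 CPM and PPA3 from 28.5 ± 13.0 to 0.206 CPM. AT1G24880 had 3 UMIs in rhd6 against 15815 in WT, a ratio of 1928 (660 to 9352). The count of genes was 5958 without WT replicate 1 and 1629 without WT replicate 3.

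The gl2 library differed from WT in markers of endodermis and of dividing cells, and little in hair genes. Of 9 endodermis markers, 4 fell (8 when adjusted over the list alone; median log2 fold change -4.50): the Casparian strip genes CASP1 (617 ± 409 to 27.2 CPM), CASP2 (109 ± 78.7 to 1.81 CPM) and CASP5 (129 ± 56.7 to 3.01 CPM) and their regulator MYB36 (70.8 ± 22.9 to 18.9 CPM). Of 10 markers of dividing cells, 6 rose (10 when adjusted over the list alone; median 1.87), such as the cyclin gene CYCB1;2 (1.39 ± 0.791 to 8.57 CPM) and the cyclin-dependent kinase gene CDKB1;1 (5.68 ± 1.04 to 16.8 CPM). The replication licensing gene CDT1A rose (log2 fold change 2.13), the only one of 5 DNA replication genes past the threshold (4 when adjusted over the list alone; median 1.38). Without WT replicate 1, 8 of 9 endodermis markers fell, and without WT replicate 2 or 3, 1 fell. Without WT replicate 2, 1 of 10 dividing markers rose; CDT1A did not pass the test without WT replicate 3.

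Root hair growth genes of gl2 stayed near WT: of 23, XTH13 and RHS8 rose (log2 fold changes 2.23 and 1.47), RHS4 fell (-1.79), and none passed when adjusted over the list alone (median -0.15). These 3 calls were lost without WT replicate 3. None of the 6 hair naming markers passed the test. Of 14 patterning regulators, MYC1 rose (2.255 ± 1.07 to 11.5 CPM; 1 when adjusted over the list alone, median 0.92). Elsewhere 1 gene rose in each of the iron (BHLH38), nitrate (NIA1, log2 fold change 2.12) and ethylene (ERF1, 1.80) lists, with medians of -0.35, -0.38 and 0.05; adjusted over the list alone, 1 nitrate gene fell as well. The camalexin synthesis gene PAD3 fell (19.2 ± 4.02 to 2.24 CPM), as did WRKY40, among 12 wounding and defence genes (median -0.70; 5 fell and 1 rose when adjusted over the list alone). MAM3 had no count in gl2 and was at least 49.1-fold lower, the only call among 8 glucosinolate genes (median -0.03). None of 4 heat shock, 3 suberin and 11 auxin genes passed the test (medians -0.39, -0.12 and 0.29, with means of 0.07, -1.73 and -0.06). Without WT replicate 2 or 3, MYC1, BHLH38, WRKY40 and ERF1 each missed the threshold. Among other cell type markers, XTH17 (non-hair), AT1G62510 (cortex), NAC086 and SUC2 (phloem) and PHO1 (stele) fell and AHK4 (stele) rose; none of 9 xylem and 5 root cap markers passed. Medians were 0.11 for non-hair (mean -0.99), -0.75 for cortex, -0.12 for phloem, -0.21 for stele, -0.61 for xylem and 0.55 for root cap markers.

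In all, 3318 of 19673 genes differed between gl2 and WT, 1455 higher and 1863 lower. PDF2.4 rose here too (0.113 ± 0.108 to 30.1 CPM), with CYP71B22 (0.198 ± 0.304 to 25.7 CPM), PDF1 (0.165 ± 0.178 to 20.5 CPM), HEMB2, named for haem synthesis (1.65 ± 1.35 to 60.6 CPM), the co-chaperone gene HOP1 (9.17 ± 2.09 to 141 CPM), AZF1, WRKY72 and GATA23 (9.60-, 9.27- and 8.79-fold). Largest among called genes with a symbol and at least 20 CPM in the higher group were the falls of the wall-modifying gene XTH17 (85.0 ± 28.4 to 0.504 CPM), MRD1 (54.8 ± 5.84 to 0.523 CPM), ATMYB30 (39.6 ± 6.48 to 0.542 CPM) and MFT (93.2 ± 28.4 to 1.42 CPM). Next came WRKY63 (62.5-fold), CASP2 (59.9-fold), the peptide gene CLE5 (48.9-fold) and PSRP6 (45.9-fold). CASP2 missed the threshold without WT replicate 2 or 3, and GATA23 without WT replicate 2. The count was 6459 without WT replicate 1, 1493 without WT replicate 2 and 894 without WT replicate 3. With the mean over cells in place of summed counts, 69.8% of 2013 called genes were higher, against 43.9% with summed counts. That scaling moved the median log2 fold change of all genes from -0.018 to 0.202.

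**Figure D2:**
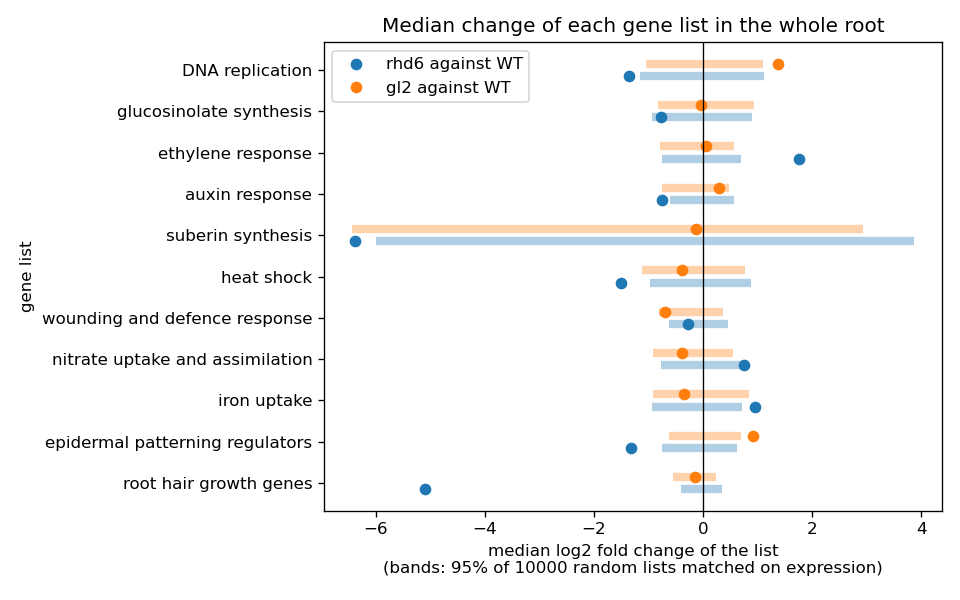
Median log2 fold change (x axis) of each test list (y axis) in the whole root, rhd6 against WT in blue and gl2 against WT in orange; bands hold 95% of 10000 random lists matched on expression. Root hair growth genes lie at -5.09 in rhd6 and -0.15 in gl2, and ethylene response genes at 1.77 and 0.05.

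Set directly against each other, the mutant libraries differed in genes of hairs, endodermis and cell division. Of 23 root hair growth genes, 21 were higher in gl2 than in rhd6 (22 when adjusted over the list alone; median log2 fold change 4.75), as were all 6 hair markers and the regulators RHD6 (4.47), RSL2 (4.24), LRL3, MYC1 and GL2, 5 of 14 (6 over the list alone). Dividing markers (8 of 10) and DNA replication genes (4 of 5; 5 over the list alone) were higher in gl2. Endodermis markers (7 of 9), xylem markers (5 of 9) and ethylene response genes (5 of 8; 7 over the list alone) were lower in gl2. CYP79B2, ABCG6, IAA19, HSFA2 and DREB2A were also higher in gl2, and NRT1.1 and GLN1;2 lower. F6H1 was lower and MYB10 higher among iron genes, and wounding genes were split between 3 higher and 3 lower. Among other markers, XTH17 (non-hair), AT1G62510 and C/VIF2 (cortex), SUC2 (phloem) and PHO1 (stele) were lower in gl2 and NAC045 (phloem) and AHK4 (stele) higher; none of 5 root cap markers passed. In this test of 1 library against 1 library on the WT spread, 6853 of 19673 genes differed, 3304 higher and 3549 lower in gl2; with the mean over cells, 67.3% of called genes were higher against 48.2%, with a shift of 0.271 in the median of all genes. Of the genes named above, PDF2.4 stood at 30.1 CPM in gl2 and 140 CPM in rhd6, MFT at 1.42 and 365 CPM, and CLE5 at 1.12 and 403 CPM.

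The lists of calls against WT overlapped. In both mutants 180 genes were higher and 286 lower, 420 were higher in rhd6 and lower in gl2, and 163 the reverse. Independent lists of the same sizes would share 150.4, 176, 192.6 and 137.5 genes. When all 5 libraries were simulated without a changed gene, at most 0.05 genes were shared on average over 20 simulations. That value says nothing of what shared controls add where many genes are called. The largest excess was among genes higher in rhd6 and lower in gl2 (420 against 192.6). A shift in the shared WT mean moves both mutants the same way, so it would not add to these. The shared WT spread helps set which genes can be called in either list, so it can add to each of these counts. With 3 WT libraries the controls could not be split into parts of at least 2. What shared controls add was therefore not measured.

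Hair-like cells were few in the rhd6 library. They made up 16.7% ± 3.35 (SD, n = 3) of WT cells, 0.611% of rhd6 cells (15 of 2455; exact 95% interval 0.342 to 1.01%) and 17.3% of gl2 cells (172 of 995; 15 to 19.8%). Non-hair-like cells made up 9.40% ± 2.71 of WT cells, 0.774% of rhd6 (19 cells; 0.467 to 1.21%) and 0.603% of gl2 (6 cells; 0.222 to 1.31%). Of the cells in both epidermal classes, hair-like cells were 64.1% ± 6.27 in WT and 96.6% in gl2 (172 of 178; 92.8 to 98.8%), and 44.1% in rhd6 (15 of 34; 27.2 to 62.1%). The mutant ratios rest on 6 (gl2) and 19 (rhd6) non-hair-like cells. They leave out unnamed cells, which may hold more of either kind. Endodermis-like cells made up 6.79% ± 3.32 of WT, 7.50% of rhd6 (6.48 to 8.61%) and 0.704% of gl2 (7 cells; 0.283 to 1.44%). Cortex-like cells were 7.61% ± 0.716 in WT, 5.58% in rhd6 (4.71 to 6.56%) and 9.75% in gl2 (7.98 to 11.8%). Phloem-like cells were 2.93% ± 1.84, 5.21% (4.37 to 6.17%) and 2.71% (1.80 to 3.92%), root cap-like cells 1.18% ± 0.647, 0.855% (0.530 to 1.31%) and 2.41% (1.55 to 3.57%), and xylem-like cells 1.1% ± 0.201, 1.22% (0.826 to 1.74%) and 1.91% (1.15 to 2.97%), in the same order. An exact permutation test of 1 library against 3 cannot pass 0.05, and no model-based test of these shares was run. Root cap-like and xylem-like shares changed with the clustering: at resolution 1.5 root cap-like shares were 5.39% (WT), 2.32% (rhd6) and 17.7% (gl2), and at resolution 0.5 xylem-like shares were 3.77, 3.22 and 4.42%.

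Many cells stayed unnamed: 54.3% ± 4.87 in WT, 78.2% in rhd6 and 64.6% in gl2. Clusters 8, 16, 19 and 20 were 84.0, 96.4, 91.9 and 98.5% rhd6 cells, and may be that library rather than a cell type. Clusters 6, 10, 16 and 21 had non-hair as their highest-scoring class but stayed under the limit for a name. Their mean log2 folds of non-hair markers were 0.195, -0.299, 0.163 and 0.652, so that score alone does not make them non-hair cells. Cluster 21 was led by the non-hair marker XTH17. It shared XTH17, AT1G14960, PER24 and AT2G16005 with the top genes of cluster 4, which was named non-hair-like. Cluster 21 may thus hold non-hair cells, though cortex markers scored nearly as high there (0.553). Cluster 6 held 22.3% of gl2 cells, 6.05, 1.79 and 2.53% of the WT libraries and 0.33% of rhd6 cells. Clusters 10, 16 and 21 held 10.0, 12.1 and 4.60% of rhd6 cells, at most 5.29, 0.19 and 1.79% of any WT library and no gl2 cell. With 78.2% of rhd6 and 64.6% of gl2 cells unnamed, the low named non-hair shares of these libraries can still not be read as a loss of non-hair cells. Cluster 15 held most cortex-like cells of WT replicate 1 (74.4%) and gl2 (66.0%), and cluster 13, led by WOX5, most of those of WT replicates 2 (85.2%) and 3 (57.6%) and rhd6 (92.0%). The cluster with the largest part of the hair-like cells was cluster 7 in WT replicate 1 (50.2%), cluster 12 in WT replicates 2 (49.8%) and 3 (39.6%), and cluster 11 in gl2 (45.3%).

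**Figure D3:**
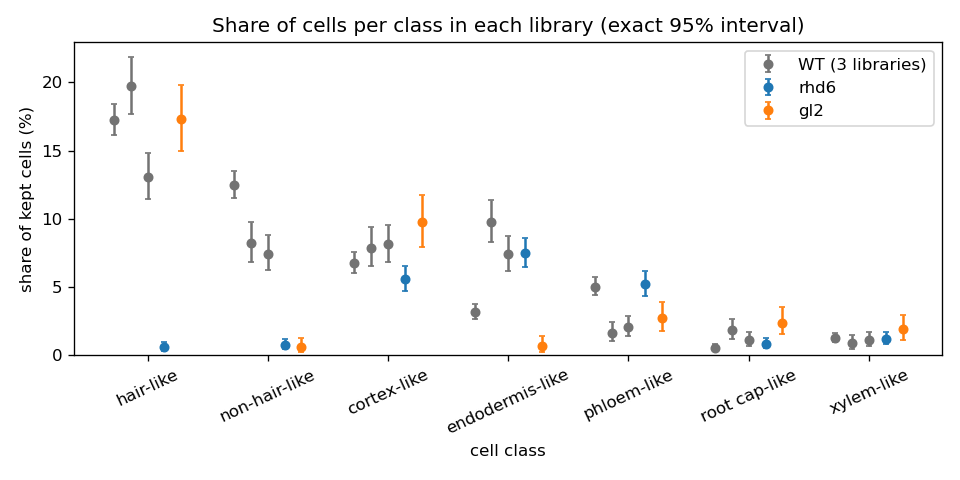
Share of kept cells (y axis, percent) in each named cell class (x axis) per library, with exact 95% binomial intervals; the 3 WT libraries are grey, rhd6 blue and gl2 orange. Hair-like cells make up 13.1 to 19.7% of the WT libraries, 0.611% of rhd6 and 17.3% of gl2, and endodermis-like cells 0.704% of gl2.

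The share of cells with hair marker transcripts was also counted without clusters. It used the same 6 markers that named the hair-like clusters, and all 6 were lower in the whole rhd6 root. A low rhd6 share largely follows from that fall and is no separate support. Neither this share nor that of hair-like cells can tell missing cells from cells without these transcripts. After thinning each cell to 2000 UMIs, at least 2 of the 6 hair markers were seen in 14.6% ± 3.24 (SD, n = 3) of WT cells, 0.652% of rhd6 cells (16 of 2455; exact 95% interval 0.373 to 1.06%) and 16.7% of gl2 cells (166 of 995; 14.4 to 19.1%). After the same thinning, cortex-like cells, which should lack these transcripts, gave none in any library (0 of 137 in rhd6, where 3 cells would be 2.19%, and 0 of 97 in gl2, where 3 cells would be 3.09%). Phloem-like cells gave 1 of 214 in WT replicate 1 and none elsewhere. Before thinning, the median depth of all cells was 31146 UMIs in rhd6 and 29514 in gl2, and that of cortex-like cells 38207 and 40180. Without thinning the shares of all cells were 25.4, 2.16 and 28.8%, but cortex-like cells then gave 22.8, 4.35 and 0% in WT replicates 1 to 3, 0% in rhd6 and 2.06% in gl2, and phloem-like cells 21% in WT replicate 1, so the unthinned shares hold background.

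Within cell classes, PDF2.4 rose in each of the 6 combinations of class and mutant tested. In cortex-like cells of rhd6, PDF2.4, SUC7 and PLC8 had no count in WT and were at least 2360-, 709- and 143-fold higher, LSU2 and CYP705A27 had none in rhd6 and were at least 88.1- and 49.3-fold lower, and AT1G24880 had 1 count against 1255, a ratio of 389 (69.7 to 15386). In cortex-like cells of gl2, PDF2.4 (at least 491-fold), HEMB2 (0.320 ± 0.341 to 245 CPM) and PGL2 (1.29 ± 0.621 to 67.8 CPM) rose, and CYP705A27 (at least 43.8-fold) and ZW9 (140 ± 14.1 to 3.04 CPM) fell. There, 422 of 14182 genes differed in rhd6, 295 higher and 127 lower, and 30 in gl2, 14 higher and 16 lower. Of the 422, 363 were called in the same direction in the whole root, and of the 30, 28, but cortex-like cells are part of those sums, so much of this overlap is built in. The rhd6 count was 1844, 2517 and 702, and the gl2 count 987, 224 and 316, without WT replicates 1, 2 and 3, so these counts rest on which WT libraries give the spread. Among lists, the nitrate genes NRT1.1 and GLN1;2 rose in cortex-like cells of rhd6 (2 of 7; 5 adjusted over the list alone; median 1.48). EBF2 (ethylene) also rose there and WER (non-hair) and AHK4 (stele) fell, and AT1G66800 (non-hair) rose in gl2.

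Endodermis-like cells of rhd6 differed from WT in 820 of 12244 genes, 401 higher and 419 lower. UGT84A3 had no count in WT and was at least 156-fold higher, PDF2.4 (1.04 ± 1.49 to 210 CPM) and PXMT1 (0.443 ± 0.457 to 25.5 CPM) rose, and AT1G24880, MRD1 and LSU2 had no count in rhd6 and were at least 244-, 213- and 146-fold lower. The count was 4300 without WT replicate 1 and 61 without WT replicate 3, where PXMT1 missed the threshold. The xylem genes XCP1 and XCP2 were higher in these sums (2 of 2 measured; 2 over the list alone; median 4.68), and free RNA from xylem cells was not measured there. Among other lists, SCR, the iron genes PDR9 and BHLH39 and the nitrate genes GLN1;2 and NRT3.1 were higher in endodermis-like sums of rhd6, and RHS13, DREB2A and GH3.3 lower. Root hair growth genes had a median of -3.71 there (10 measured), and free RNA from hair cells was not measured. Hair-like cells of gl2 differed in 1340 of 13786 genes, 775 higher and 565 lower. The triterpene synthase gene BARS1 had no count in WT and was at least 1090-fold higher, AT1G21110 (0.138 ± 0.135 to 24.4 CPM) and WRKY72 (1.01 ± 0.634 to 32.5 CPM) rose, and AT2G17570 fell from 30 ± 1.26 to 0.499 CPM. HYH had 2 counts in gl2 against 1471 in WT, a ratio of 112 (30.9 to 925), and GDPD4 3 against 2265, a ratio of 115 (39.2 to 557). Of 23 root hair growth genes, 5 rose there and none fell (5 rose and 1 fell when adjusted over the list alone; median 0.38): XTH13 (26.8 ± 10.2 to 190.9 CPM), RHS8 (18.7 ± 2.60 to 86.4 CPM), LRX2, RHS9 and CSLD3, the latter needed for wall growth in hairs. Of other list members, COBL9, AT1G66800, AHK4, BHLH38, BHLH39, NIA1, WRKY33, HSFA2, IAA2 and CDT1A rose there, and XTH17, CASP1, NRT1.1 and MAM3 fell. The count was 4758, 640 and 747 without WT replicates 1, 2 and 3.

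Phloem-like cells differed in 1213 of 10138 genes in rhd6 (586 higher, 627 lower) and 165 in gl2 (61 higher, 104 lower). In rhd6, PDF2.4 was at least 135-fold higher and AZF3 rose (0.744 ± 0.649 to 32.5 CPM), as did HSFB3, with 2 counts in WT against 111, a ratio of 88.3 (23.9 to 738). MRD1 and LSU2 were at least 75.3- and 69.1-fold lower, and AT1G24880 had 1 count against 595, a ratio of 374 (66.9 to 14798). In the sums of these cells in rhd6, the endodermis markers CASP1, CASP5, PER64 and ESB1 were higher (4 of 5; 5 adjusted over the list alone; median 2.98), and free RNA from endodermis cells was not measured there. The ethylene genes EBF1, EBF2 and CTR1 were higher as well, as were APL, SAPL, C/VIF2, BHLH39, GLN1;2 and TCH3, and RHS13, ADF8, HSFA2, DREB2A, CPC, AHK4, FER1 and IAA5 were lower. Root hair growth genes had a median of -3.36 in these sums (6 measured), and free RNA from hair cells was not measured. In gl2, HEMB2 and PDF2.4 were at least 215- and 113-fold higher and GATA23 rose (2.38 ± 3.40 to 154 CPM), as did NIA1, WRKY33 and TCH4, while AOC2, WRKY63 and LSU1 were at least 36.8-, 11.8- and 10.2-fold lower. The rhd6 count was 2234 without WT replicate 3, and the gl2 count was 559 without WT replicate 1 and 626 without WT replicate 3. Non-hair-like, root cap-like and xylem-like cells, hair-like cells of rhd6 and endodermis-like cells of gl2 had under 20 cells in a library needed and were not tested.

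In WT, hair-like and non-hair-like cells were compared within the same 3 libraries, to describe the transcripts that part these neighbouring cell types. All 23 root hair growth genes measured were higher in hair-like cells (23 when adjusted over the list alone; median log2 fold change 7.53), such as RHS13 (2921 ± 1600 against 6.95 ± 5.02 CPM, SD, n = 3) and RHS15 (195 ± 107 against 0.259 ± 0.224 CPM). Of 8 patterning regulators, 5 were higher and 3 lower in hair-like cells, among them the non-hair gene TRY at 0.445 ± 0.412 against 25.5 ± 3.34 CPM. All 4 heat shock genes and 8 of 9 wounding and defence genes were lower in hair-like cells (medians -2.42 and -0.75). Iron (1 higher and 1 lower of 5), nitrate (3 and 3 of 8), auxin (1 and 3 of 10) and glucosinolate genes (3 and 1 of 5) went both ways, 2 of 8 ethylene genes were lower and none higher, and none of 2 DNA replication genes passed, with the same counts over the list alone except glucosinolate (3 and 2). Other large rises in hair-like cells were GRF11 (log2 fold change 8.94), the ROP effector gene RIC1 (8.53), PER73 (8.40), AT5G05500 (8.34), XTH26 (8.29) and TET12 (8.25). Large falls were KCS5, a gene of fatty acid elongation (0.260 ± 0.451 against 57.7 ± 6.02 CPM), MLP34 (log2 fold change -6.91), ATMYB30 (-6.43), EXPA12 (-6.42), MRN1 (-5.70), ZPR3 (-5.68) and CYP705A30 (-5.40). In all, 7373 of 13142 genes differed, 3747 higher and 3626 lower in hair-like cells, and 4522 differed without WT replicate 3. The classes were found from the same cells, so a difference between them is partly built in, also for genes left out of the clustering features.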

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

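Chosen only after values were seen were the tests of whether a change differed between classes, the 32-fold and 8-fold limits, the position tests, the test of cortex-like shares and the tests of fewer endodermis cells in gl2.

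The change from WT differed between cell classes for some genes, by a test of the difference itself with edgeR. In rhd6 it differed between cortex-like and endodermis-like cells for 5 genes, CXE5, AT2G15340, H2AV, RABA1E and AT3G59710. It also differed between cortex-like and phloem-like cells for 5 genes, AT4G01670, SUC1, AT1G60010, CYP85A2 and AT3G27630, and between endodermis-like and phloem-like cells for 384. In gl2 it differed between hair-like and phloem-like cells for 51 genes, among them OCT6, XTH4 and AT1G43910, named for their small adjusted p. Between cortex-like and hair-like or phloem-like cells of gl2, edgeR called 0 genes, with 1380 and 733 at an unadjusted p under 0.05. These differences rest on 1 library per mutant, and no explanation was tested for them.

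Of the genes at least 32-fold lower in the whole root (237 in gl2 and 345 in rhd6), 50 and 38 were tested in cortex-like cells and held there in WT at or above the whole-root level; choosing them so forces a fall inside these cells, so the fold there, the test set in advance, was not used. With cortex levels unchanged, a 32-fold fall would need cortex-like cells to make up at most 3.125% of a mutant library, but they made up 9.75% of gl2 (exact 95% interval 7.98 to 11.8%) and 5.58% of rhd6 (4.71 to 6.56%), which argues against a changed mix of the named classes as the whole cause. For genes that WT cortex-like cells hold below the whole-root level, the median log2 fold changes inside these cells were -6.58 (62 genes) and -6.64 (61 genes), past the limit set in advance, but a changed mix stays open for them, because that limit overlooked free RNA, which could carry a fall in other classes into cortex-like sums. Markers of other classes had negative medians there (-2.92 for root hair growth genes in rhd6 and -3.81 for endodermis markers in gl2), but with edgeR 0 of 11 and 0 of 8 passed over all genes tested, and 6 and 6 fell over the list alone, so this ground, found after the values were seen, is weak. That judgement rests on cortex-like sums alone. In rhd6, root hair growth genes also had negative medians in endodermis-like (-3.71, 10 genes) and phloem-like sums (-3.36, 6 genes). A changed mix of clusters inside the cortex-like class and lost sequence matches in the mutants' accessions also stay open.

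Of the 16 genes named by size, 9 in rhd6 and 7 in gl2 lie on chromosome 1, where RHD6 and GL2 lie. Of genes tested in cortex-like cells, 26.1% lie there. SUC7 (AT1G66570) and PXMT1 (AT1G66700), higher in rhd6, have locus numbers near that of RHD6 (AT1G66470). WRKY63 (AT1G66600), lower in gl2, does too. Background sequence carried along with the rhd6 allele was therefore a candidate explanation. The test used another set, the 257 genes called at 8-fold or more in cortex-like rhd6 cells. Of these, 10.9% lay within 5 Mb of RHD6 against 9.50% of tested genes. Of 10000 rotations of the gene order, 24.41% were as high, which argues against a cluster of those genes over this window. Whether single genes closer to RHD6 changed with the allele was not tested. In gl2 the value was 10.2% in hair-like cells (333 genes) and 15.1% in phloem-like cells (73 genes), each against 9.20% of tested genes, with 41.31% and 11.07% of rotations as high. Over this window rhd6 showed no position pattern for an effect common to both mutants to explain. The gl2 values leave such an effect open.

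In gl2, endodermis markers were lower and dividing-cell markers higher. After all libraries were thinned to 1 total, 5 endodermis markers were lower and 6 dividing markers higher, which argues against library depth. Losing all endodermis-like cells, at most 9.75% of a WT library, would raise all other classes by 0.15 on the log2 scale, while dividing markers had a median of 1.87 (95% of random lists from -0.67 to 0.89), which argues against fewer endodermis cells as the cause of their rise. For the endodermis markers themselves this stays open, as endodermis-like cells made up 0.704% of gl2 and 7 cells were too few to test levels inside the class. A larger share of dividing cells stays open too. Cluster 26, with a mean log2 fold of dividing markers of 5.02, held 2.51% of gl2 cells. It held 0.38, 0.41 and 0.68% of the WT libraries. These shares go that way, but the cluster was picked after results were seen and levels inside it were not tested. With 1 gl2 library, the gl2 genotype and its accession background cannot be told apart.

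For hair-like against non-hair-like cells in WT, 1 of the 10 splits of the 6 sums gave as many genes, the real one with 7373. The highest of the others, tested with edgeR, gave 0. So few splits cannot give a share under 0.05.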

How the results depend on the processing

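All alternatives reported here were chosen before the data were examined. Among counts and shares, 185 values stayed within their limit and 63 moved. Of 172 named gene results, 123 passed the threshold and 91 of these kept it under every alternative that gave a value for them. Over all results and alternatives, 67 values lost the threshold and 59 gained it, each with an unchanged direction. Of results past the threshold in the main fit, 0 changed direction under an alternative. Changes of direction were not counted for whole-root results that missed the threshold. With the mean over cells tested by limma, 1805 genes changed in rhd6 and 2013 in gl2, and 0 root hair growth genes were higher in gl2; that count was 1 with DESeq2 size factors and 1 with no low-count filter. With no filter, 1173 (rhd6) and 337 (gl2) genes changed in cortex-like, 1299 in endodermis-like, and 1892 (rhd6) and 509 (gl2) in phloem-like cells. With classes from all highly variable genes, 80 changed in cortex-like cells of gl2.

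With each WT library left out in turn, the counts ranged from 1629 to 5958 (rhd6) and 894 to 6459 (gl2) in the whole root, 0 to 3 for root hair growth genes higher in gl2, 702 to 2517 (cortex-like, rhd6), 224 to 987 (cortex-like, gl2), 61 to 4300 (endodermis-like), 640 to 4758 (hair-like), 1080 to 2234 (phloem-like, rhd6), 215 to 626 (phloem-like, gl2) and 4522 to 7080 (hair-like against non-hair-like).

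Shares with all highly variable genes were 6.60% (cortex-like, rhd6), 12.9% (hair-like, gl2), 12.7, 1.59 and 0.201% (non-hair-like in WT, rhd6 and gl2), 5.53% (root cap-like, gl2) and 76.1% (unnamed, rhd6). Phloem-like shares were 3.46% (rhd6) and 1.71% (gl2) at resolutions 0.5 and 1.5, and 3.71 and 1.60% with doublet calls kept. Xylem-like shares in WT, rhd6 and gl2 were 3.77, 3.22 and 4.42% at resolution 0.5 and 4.37, 4.07 and 4.79% with doublet calls kept. At resolution 1.5, root cap-like shares were 5.39, 2.32 and 17.7%, and the unnamed share of gl2 50.7%. The share of cells with hair marker transcripts was 13.97% in gl2 at 1000 UMIs, 25.4, 2.16 and 28.8% (WT, rhd6, gl2) without thinning, where cortex-like cells gave up to 22.8%, 19.6, 1.83 and 22.8% with at least 1 marker (cortex-like cells up to 10.7%), and 13.8% in gl2 with at least 3. For values that moved, the cause was not tested. At this number of cells, a class seen in no gl2 cell could still have made up 0.302% of them.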

Other observations

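The test of each WT library in a mutant's place and the clusters described here were chosen only after results were seen.

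A larger share of the gl2 library than of the other libraries lay in 2 clusters that took no class. Dividing markers were not used to name clusters, and their mean log2 fold in cluster 26 was 5.02. Cluster 26, with the cell division genes KN (KNOLLE, needed for the cell plate), MAD2 and CDC20-1 among its top genes, made up 2.51% of gl2 cells, 0.38, 0.41 and 0.68% of the WT libraries and 0.20% of rhd6 cells. Cluster 6, with GSTU14 and the ribosomal protein genes RPS12C and RPL9D among its top genes, made up 22.3% of gl2 cells, 6.05, 1.79 and 2.53% of the WT libraries and 0.33% of rhd6 cells, at a median of 78982.5 UMIs. In rhd6, cluster 20, 98.5% rhd6 cells, was led by CYP85A2 and held the endodermis regulator gene MYB36 among its top genes.

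When a WT library was set in a mutant's place, edgeR called 580 genes for WT replicate 1, against 6018 for rhd6 and 6486 for gl2 in the same fit. Of the root hair growth genes, 5 were lower in WT replicate 1 than in the other WT libraries, and 22 were lower in rhd6. For WT replicates 2 and 3 it called 0, also among root hair growth genes, with 1299 and 380 genes at an unadjusted p under 0.05.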
